A study of Mus musculus with 95 samples.

How the data were processed

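The analysis used 3 kinds of deposited values. The first is the expected count per gene, which as deposited had been estimated by the authors from reads aligned to mm10 and was not scaled to depth. It was given for 39179 genes in each of 95 libraries, and 32.2% of the values above 1 were not whole numbers, and all were rounded to whole counts before the count tests. The second is FPKM per gene in the same libraries, which as deposited had been scaled by the authors to gene length and library size, and which was used only in alternatives. The third kind holds per-library values: the alignment count, used for depth alone, and the CAG repeat number of each animal, which the authors gave as other information. The length implied by count and FPKM varied by 1.49% (coefficient of variation) over 6731 genes with over 200 counts, so the 2 units describe the same reads. Per the submitters' processing notes, base calls were made with CASAVA 1.8.2 and the genome was mm10; the aligner, the counting program and the annotation are not given in the sources used here. Gene identifiers were matched to symbols and coordinates of GENCODE M21 (GRCm38, the assembly of mm10), which named 37607 of them; 1572 stayed unnamed and held at most 0.329% of the counts of a library. Whether the libraries keep strand was not stated, so counts of overlapping genes on opposite strands are not separable here.

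Line, genotype, tissue, sex and replicate came from the sample titles, per the labels, and animals were followed across tissues by their identifiers: 32 animals, 31 with all 3 tissues. RNA came from tissue flash frozen on dry ice and was extracted with miRNeasy, per the labels. Groups were 4 per line, genotype and sex, except the neo-out Het males of the striatum with 3; their first replicate was not analysed here. Replicates of the same group were compared for duplicated libraries: over 141 pairs the lowest chi-square per gene was 4.33, where copies of 1 library would lie near 1. No library was removed from the tests.

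Depth was even in brain and wider in liver. Expected counts per library were 31.02 to 43.99 M in cortex (median 35.48), 33.12 to 68.36 M in liver (median 40.6) and 31.1 to 43.05 M in striatum (median 35.97). Alignment counts were 80.61 to 114.2, 86.17 to 185.9 and 81.83 to 113.4 M. Mitochondrial genes held 9.621 to 12.33% of counts in cortex, 7.665 to 11.9% in liver and 12.44 to 15.22% in striatum, and the 10 highest genes held 9.115 to 11.64%, 16.98 to 22.13% and 11.74 to 14.44%.

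Each tissue was analysed alone with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the cell of line, genotype and sex as group, scaled by TMM and fitted with a quasi-likelihood negative binomial model that had 1 coefficient per cell; all libraries of a tissue shared the estimate of spread. Het against wild type in a line is the mean of the female and male differences; the line difference, the wild-type comparison, the comparison of the Het groups, both lines together and genotype by sex (female effect less male effect) are contrasts of the same fit. P values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at adjusted p below 0.05. No fold-change threshold was set. Errors are standard errors from the fit, and CPM are mean ± SD over libraries. The log2 CPM used in scores took a prior count of 2.

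Named genes follow a rule set in advance: Htt always; the 8 highest and 8 lowest log2 fold changes of a contrast among called genes with a mean of at least 1 CPM and the same sign in both sexes; up to 4 members of each gene list with the smallest p; and up to 5 genes per direction for the line difference, the wild-type comparison and genotype by sex. No gene was named whose lower group held fewer than 3 counts in all. The 42 gene lists were written before the data were examined, with 28 for striatum, 28 for cortex and 29 for liver, as were the contrasts, the test and most of the alternatives. Lists were tested with camera in limma 3.58.1 on voom values with its preset correlation of 0.01, and again with the correlation estimated from the data. Their p values were adjusted by Benjamini-Hochberg within a tissue in 2 families: Het against wild type (each line and both) with the line difference, and, added later, the wild-type comparison with genotype by sex. "Adjusted over the list alone" means Benjamini-Hochberg over the members of 1 list. A list with too few measured members gave no test, so 27, 27 and 28 lists were tested.

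Htt levels were also compared by exact permutation tests of mean log2 CPM within tissue (12 comparisons adjusted together) and across tissues by permutation of genotype within line and sex (9 comparisons; 100000 draws with both lines together, all arrangements within a line). The effect ratio of the lines is the mean signed change in neo-out over that in neo-in, over genes called with both lines together, so that neither line chose the genes, and it was computed where at least 20 genes were called; its error is a jackknife over libraries and its p comes from 100000 permutations of line within genotype and sex. Expected overlaps assume independent calls. The CAG repeat number was correlated with the striatal response in neo-out Het mice and, as a later addition, in each line within sex (values less their sex mean, all permutations within sex).

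The alternatives set in advance were RLE size factors, no low-count filter, a strict filter (1 CPM in at least 8 libraries), legacy quasi-likelihood, DESeq2 1.42.0, voom with quality weights, FPKM with a pseudocount of 0.1 or 1 and without a filter, sex as an additive term, libraries of a line alone, a replicate block, and leaving out each library in turn. After the results had been seen 4 more were added. The first left out libraries that carry markers of other tissue or inflammation. In striatum this meant over 100 CPM of Slc17a7 or 500 of Ttr. In cortex it was over 4 CPM of Drd2 or 500 of Ttr, and in liver over 1000 CPM of Lcn2. The second took the clock score of the same animal as a covariate, from liver for striatum and cortex, and from both brain tissues for liver. The third was a term for 23 libraries with a library number of 59 and above or an index suffix. The last was the level of Drd2 and Adora2a as a striatal share in cortex. The clock score is the mean log2 CPM of 5 genes less that of 4 others.

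Each contrast was repeated in 100 splits, the real 1 included, that permuted genotype within line and sex, or line within genotype and sex. A test of the method simulated negative binomial counts with the observed depths and spreads and changed 200 genes of at least 1 CPM in neo-in Het libraries, 50 at each of the folds 1.25, 1.5, 2 and 4. Of these, 66, 84, 100 and 100% were recovered for Het against wild type in striatum, 68, 88, 100 and 98% in cortex, and 42, 66, 96 and 100% in liver. For the line difference the shares were 38, 78, 98 and 100% in striatum, 54, 76, 96 and 98% in cortex, and 16, 50, 88 and 98% in liver. Unchanged genes called beside these numbered 10, 6 and 3 for Het against wild type in striatum, cortex and liver, and 15, 11 and 6 for the line difference, a share above 0.05 of the calls in striatum (both tests) and cortex (line difference). Other calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Reads, small RNA and protein were not used here, and some single-gene results are not reported here.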

Results

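Messenger RNA was sequenced from striatum, cortex and liver (each labelled left) of 6-month-old heterozygous zQ175 knock-in mice, which carry an expanded CAG repeat in Htt. The mice came from 2 lines, 1 with and 1 without the neo cassette (neo-in and neo-out below), and wild-type littermates of each line were sequenced with them. Each line and genotype had 4 males and 4 females, which gave 95 libraries from 32 animals. In the striatum the neo-out Het group had 7 libraries, since the first replicate of its males was not analysed here. Expected counts per library summed to between 31.02 and 68.36 M. Xist was at least 1.03e+03 CPM (counts scaled to library size) in each female striatum and at most 2.48 in males, so the measured sex matched the stated sex. Each animal's CAG repeat number was also given: 191.2 ± 7.592 (mean ± SD) in neo-in Het mice and 197.8 ± 9.362 in neo-out Het mice, 8 animals each. In the neo-in line the repeat numbers of females (181 to 189) and males (195 to 200) did not overlap, so repeat length differed with sex there.

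The first question was whether striatal Htt transcript was lower in Het mice and whether the 2 lines differed in it. Htt (ENSMUSG00000029104, chromosome 5, start 34761740, end 34912534, plus strand) fell in the neo-in striatum from 196 ± 7.03 CPM in wild type to 149 ± 14.6 in Het mice, or 75.9% of wild type, n = 8 and 8. In the neo-out striatum it fell from 195 ± 16.7 CPM to 166 ± 7.11, or 85.6%, n = 8 and 7. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment the changes were -0.39 ± 0.05 (log2 ± SE, adjusted p = 1.16e-06) and -0.23 ± 0.05 (adjusted p = 0.00237). All 8 neo-in Het values lay below all wild-type values of that line (exact permutation test p = 0.000155, 0.000465 after adjustment over 12 comparisons), and the neo-out exact p was 0.00311 (adjusted 0.00533). Htt was 0.16 log2 higher in neo-out than in neo-in Het striatum by an exact test (p = 0.0087, adjusted 0.013). Adjusting over all genes, edgeR gave an adjusted p of 0.167 here and 0.995 for the difference between the 2 Het effects (0.17 ± 0.07). Neither excludes a difference in Htt. The wild-type groups did not differ in Htt (-0.01, exact permutation p = 0.928). Counts of Htt do not separate the 2 alleles.

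**Figure D1:**
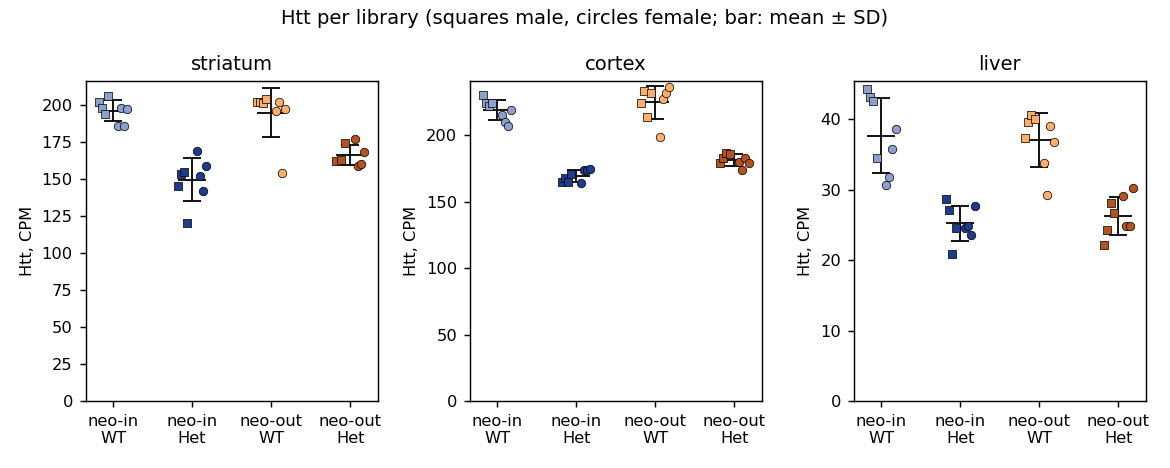
Htt in CPM for each library, by tissue, line and genotype. Het means lie below wild type in all 3 tissues, at 75.9% in neo-in and 85.6% in neo-out striatum.

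Which striatal genes changed in neo-in Het mice? Of 17703 genes tested, 1592 rose and 1904 fell, 8 Het against 8 wild-type libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). With the FPKM values in place of counts the split was 2834 up and 1335 down; the cause of the shift was not tested. Most changes were small, with a median absolute log2 change of 0.2562 among called genes, and 157 genes rose and 325 fell by 1.5-fold or more. Among genes with a mean of at least 1 CPM and the same sign in both sexes, the largest decrease was in Gpx6, a glutathione peroxidase (-2.03 ± 0.13, adjusted p = 1.34e-12). Ryr1, a calcium release channel, fell from 131 ± 23.8 to 35.6 ± 4.93 CPM (-1.88 ± 0.10, adjusted p = 2.02e-13). Also lower were Abhd11os (-1.91 ± 0.14), Sec14l3 (-1.79 ± 0.13) and the membrane transporter Slc4a11 (-1.76 ± 0.12). Wt1, a developmental zinc-finger transcription factor, was at 7 counts over the 8 wild-type libraries and at 620 in Het mice (+6.65 ± 0.31, adjusted p = 6.82e-18). Sfmbt2, a Polycomb-group gene, rose from 4.83 ± 0.666 to 12.6 ± 1.06 CPM (+1.37 ± 0.07, adjusted p = 5.11e-15). Abhd1 rose by 1.42 ± 0.09 (adjusted p = 3.96e-12), the desmosome gene Dsp by 1.54 ± 0.21 and Tnnt2, a troponin, by 1.20 ± 0.12. Abhd11os and Gm9754 (-1.80 ± 0.14) are annotated antisense or opposite other genes, and whether the libraries keep strand was not stated.

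Projection neurons of the striatum, the medium spiny neurons (MSN), have marker genes that nearly all fell in the neo-in line. All 34 shared MSN identity genes measured fell, 34 also when adjusted over the list alone (median -0.63, camera adjusted p = 1.2e-47, and adjusted p = 0.0209 with an estimated correlation). Examples were Ddit4l (-1.40 ± 0.08), the sodium channel subunit Scn4b (-1.18 ± 0.07) and the adenylyl cyclase Adcy5 (-0.77 ± 0.05). Of 8 indirect-pathway markers 6 fell, 6 adjusted over the list alone, among them Penk, which encodes proenkephalin (-1.11 ± 0.05, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 6.31e-16), Adora2a (-0.69 ± 0.07) and Drd2 (-0.66 ± 0.06). The indirect-pathway list had a camera adjusted p of 1.3e-08, and adjusted p = 0.0209 with an estimated correlation. Of 8 direct-pathway markers 4 fell and 2 rose (5 and 2 adjusted over the list alone); Drd1 fell by 0.64 ± 0.07 and Pdyn by 0.42 ± 0.06. That list had a camera adjusted p of 0.0144 but adjusted p = 0.283 with an estimated correlation. Interneuron markers were not called as a list (camera adjusted p = 0.285), with 2 of 11 lower and 0 higher.

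Clustered beta protocadherins rose, as did 3 of 10 measured transcription factors that are normally silent in adult neurons. Of 21 beta protocadherins measured 15 rose and 0 fell (16 adjusted over the list alone, median 0.34, camera adjusted p = 1.55e-11, and adjusted p = 0.0209 with an estimated correlation), for instance Pcdhb9 (+0.61 ± 0.06) and Pcdhb13 (+0.60 ± 0.07). These genes resemble each other, and how reads shared among them were counted was not stated. Of 38 listed developmental transcription factors 10 passed the count filter and 3 rose, 3 adjusted over the list alone (camera adjusted p = 0.00461, and adjusted p = 0.023 with an estimated correlation); Onecut1 rose by 4.81 ± 0.35 (edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 7.19e-13).

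Immediate early genes were lower in neo-in Het striatum, with 9 of 16 lower and 0 higher (12 adjusted over the list alone, median -0.52, camera adjusted p = 1.75e-05), but adjusted p = 0.337 with an estimated correlation. Egr2 fell by 1.81 ± 0.25, Nr4a1 by 0.83 ± 0.18 and Egr1 by 0.60 ± 0.12 (edgeR quasi-likelihood). These values are means of both sexes, and the sex difference of the list is given below. Fos, for example, stood at 17 to 20.4 CPM in Het females and 8.88 to 24.3 in wild-type females. In males it stood at 3.95 to 17 in Het and 7.51 to 41.9 in wild type. Of 16 clock genes 8 fell and 0 rose (9 and 1 adjusted over the list alone, camera adjusted p = 3.39e-06, and adjusted p = 0.0717 with an estimated correlation), among them Npas2 (-0.63 ± 0.06), Dbp (-0.60 ± 0.06) and Ciart (-0.59 ± 0.08). Endothelial and mural markers had 6 of 14 lower (9 adjusted over the list alone), with Flt1 at -0.30 and Rgs5 at -0.31 (camera adjusted p = 0.000619, and adjusted p = 0.108 with an estimated correlation). Of the neurotrophin and activity genes 6 of 11 fell and 0 rose (6 and 1 adjusted over the list alone), with Inhba at -0.88 ± 0.14 (camera adjusted p = 0.00648, and adjusted p = 0.317 with an estimated correlation). Of 13 mismatch repair genes 3 rose, 3 adjusted over the list alone, with Msh3 at +0.16 ± 0.05 and Lig1 at +0.20 (camera adjusted p = 0.00612, and adjusted p = 0.265 with an estimated correlation). Among 25 measured genes flanking Htt 4 rose and 5 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.594), the furthest being Zfyve28 (-0.50 ± 0.04) and Adra2c (-0.45). Of 27 lists tested 11 passed camera at 0.05 and 4 did so with an estimated correlation.

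Did the line without the cassette show the same striatal changes? In neo-out Het mice 1569 genes rose and 1647 fell of 17703, 7 Het against 8 wild-type libraries (edgeR quasi-likelihood, Benjamini-Hochberg), and 117 rose and 361 fell by 1.5-fold or more. With FPKM values the split was 2426 up and 1276 down. The extremes were largely the ones of the neo-in line. Gpx6 fell by 2.99 ± 0.15 (adjusted p = 2e-14), Tmprss6, a serine protease gene, by 2.55 ± 0.27. Ryr1 fell from 121 ± 20.1 to 30.8 ± 4.22 CPM (-2.01 ± 0.11, adjusted p = 1.34e-13), Abhd11os by 2.18 ± 0.16 and Gm9754 by 2.12 ± 0.16. Wt1 rose from 19 to 572 counts (+4.99 ± 0.25, adjusted p = 6.88e-17). Sfmbt2 rose by 1.52 ± 0.07 (adjusted p = 6.45e-16), Abhd1 by 1.41 ± 0.10 (adjusted p = 1.11e-11), Dsp by 1.74 ± 0.21 and Tnnt2 by 1.09 ± 0.12. Ttr, a choroid plexus transcript, was called lower (-2.22 ± 0.69, adjusted p = 0.0237), but 1 neo-out wild-type library held 1.35e+03 CPM of it, and without the libraries with high Slc17a7 or Ttr it was at -0.90 (adjusted p = 0.194). Leaving out 1 library at a time kept the count between 2480 and 3375, and the liver clock score of each animal as a covariate lowered it to 1370. Among the animals with a striatum library, that score did not overlap between the genotypes of this line (0.23 to 3.06 in Het, -3.39 to -0.73 in wild type). For the 3216 genes the covariate left the median change at 0.274 (from 0.257) while the median error rose from 0.0596 to 0.093.

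In the neo-out striatum all 34 shared MSN genes again fell, 34 adjusted over the list alone (median -0.56, camera adjusted p = 1.16e-44, and adjusted p = 0.0209 with an estimated correlation), with Ddit4l at -1.78 ± 0.09 and Scn4b at -1.27 ± 0.08. Of 8 indirect-pathway markers 6 fell, 6 adjusted over the list alone (camera adjusted p = 4.81e-10, and adjusted p = 0.0209 with an estimated correlation), with Penk at -1.19 ± 0.05 and Adora2a at -0.90 ± 0.08. The direct-pathway list had 4 lower and 2 higher of 8 (5 and 3 adjusted over the list alone, camera adjusted p = 0.032, and adjusted p = 0.337 with an estimated correlation), and Drd1 fell by 0.67 ± 0.07. Beta protocadherins rose in 18 of 21 (19 adjusted over the list alone, median 0.53, camera adjusted p = 9.78e-17, and adjusted p = 0.00565 with an estimated correlation), with Pcdhb3 at +0.79 ± 0.10 and Pcdhb19 at +0.70 ± 0.07. Developmental transcription factors rose in 4 of 10, 4 adjusted over the list alone (camera adjusted p = 0.000991, and adjusted p = 0.0209 with an estimated correlation), with Onecut1 at +3.48 ± 0.28.

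Glial and lipid lists passed camera with its preset correlation in the neo-out striatum. Oligodendrocyte and myelin genes had 7 of 15 lower, 7 adjusted over the list alone, with Ugt8a at -0.43 ± 0.07 (camera adjusted p = 0.00169, and adjusted p = 0.408 with an estimated correlation). Cholesterol synthesis genes had 5 of 21 lower and 0 higher (6 and 1 adjusted over the list alone), led by the sterol-regulated Insig1 at -0.47 ± 0.06 (camera adjusted p = 0.00223, and adjusted p = 0.42 with an estimated correlation). Astrocyte markers had 7 lower and 1 higher of 15 (9 and 1 adjusted over the list alone), with Slc1a2, a glutamate transporter, at -0.31 ± 0.05 and S100b at +0.27 ± 0.05 (camera adjusted p = 0.00291, and adjusted p = 0.167 with an estimated correlation). In neo-in Het striatum the astrocyte list had a camera adjusted p of 0.0611 and the oligodendrocyte list 0.449. Tested between the lines, the astrocyte list did not differ (camera adjusted p = 0.107), and the oligodendrocyte list did (camera adjusted p = 2.46e-05), though adjusted p = 0.324 with an estimated correlation. Immediate early genes, as a mean of both sexes, had 9 of 16 lower and 0 higher (11 adjusted over the list alone), with Egr2 at -1.83 ± 0.26. That list had a camera adjusted p of 8.53e-06, and adjusted p = 0.324 with an estimated correlation. Fos stood at 4.23 to 11.5 CPM in Het females and 17.7 to 26.2 in wild-type females. In males it stood at 10.5 to 19 in Het and 8.19 to 12.5 in wild type. Markers of other tissue were lower beside these lists: 2 of 12 choroid plexus genes (median -0.69, 4 over the list alone, camera adjusted p = 0.0299, and adjusted p = 0.597 with an estimated correlation) and 3 of 20 cortical excitatory markers (camera adjusted p = 0.285). Of the 4 libraries high in Slc17a7 or Ttr 3 were neo-out wild type, and without the 4 Ugt8a was at -0.48, Insig1 at -0.45 and Slc1a2 at -0.36, all still called. Of 27 lists 13 passed camera and 4 did so with an estimated correlation.

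**Figure D2:**
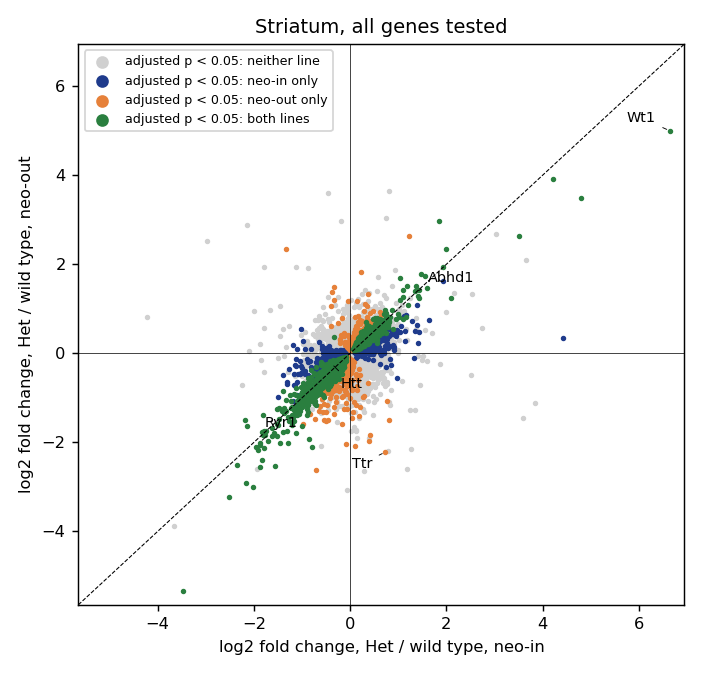
Striatal log2 fold change, Het against wild type, neo-in on the horizontal and neo-out on the vertical axis, 1 point per gene. Over all genes r = 0.56, and 97.6% of genes called in the neo-in line had the same sign in the neo-out line.

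Did the 2 lines differ in their striatal response? The direct test of the difference called 1 gene of 17703, Nr1d1, a clock repressor (difference 0.62 ± 0.08, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.00049). An unadjusted p below 0.05 was held by 816 genes, and DESeq2 called 3. With the clock covariate 0 genes were called, and the Nr1d1 difference was 0.439 with an error of 0.126. Of 100 splits of the lines, the real 1 included, 5 called at least 1 gene. Nr1d1 fell in the neo-in line from 91.2 ± 11.2 to 64.8 ± 6.58 CPM, and the neo-out means were 63.2 ± 4.2 and 69.3 ± 4.53. The lines shared 915 genes called higher (141 expected) and 1204 called lower (177 expected), and 1 gene was called in opposite directions. Over the 5750 genes called with both lines together, the mean size of the change was 0.279 in neo-in and 0.283 in neo-out, a ratio of 1.02 ± 0.0671 (permutation p = 0.903; 0.984 to 1.04 with 1 library left out). Camera called 9 of 27 lists between the lines, for instance the beta protocadherins (+0.11, adjusted p = 0.00307; adjusted p = 0.337 with an estimated correlation) and the cholesterol genes (-0.15, adjusted p = 1.47e-10; adjusted p = 0.0718 with an estimated correlation), and 0 with an estimated correlation.

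Wild-type striatum of the 2 lines was compared to learn what differed without the allele. Neo-out wild type had 34 genes higher and 53 lower than neo-in wild type, 8 against 8 libraries (edgeR quasi-likelihood, Benjamini-Hochberg). Of 16 clock genes 2 were higher and 4 lower (3 and 8 adjusted over the list alone, camera adjusted p = 0.00294, and adjusted p = 0.466 with an estimated correlation). Dbp (-0.65 ± 0.06, adjusted p = 1.12e-06), Ciart (-0.63) and Nr1d1 (-0.53, adjusted p = 2.23e-06) were lower, and Arntl, which encodes BMAL1, was higher (+0.56 ± 0.06, adjusted p = 5.34e-06). Cholesterol synthesis genes were higher in neo-out wild type, with 7 of 21 called and 15 adjusted over the list alone. That list had a camera adjusted p of 1.01e-20, and adjusted p = 0.0371 with an estimated correlation. Hmgcs1 was at +0.32 and Fdps at +0.27. The line difference of this list given above therefore does not show whether wild-type or Het mice carry it. The count fell to 46 without neo-in wild-type male 4, lay at 52 to 56 without neo-in female 1 or neo-out female 4, male 1, male 3 or male 4, and rose to 139 without neo-in female 2. It was 0 with the clock covariate (median change 0.338 to 0.273, error 0.0635 to 0.133) and 15 without the 4 libraries high in Slc17a7 or Ttr, all wild type.

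Genotype by sex, the Het effect in females less that in males, was tested in the striatum to ask whether the sexes responded differently. In the neo-in line 1 gene was called, Pvr (0.58 ± 0.10, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0278), and 11 of the single-library omissions ended that call. In the neo-out line 1 gene was called, Zbtb16 (2.28 ± 0.37, adjusted p = 0.0226), and 3 omissions ended it. The counts ranged over 0 to 24 and 0 to 13 with 1 library left out, the highest without neo-in wild-type female 2 and neo-out Het male 4. Immediate early genes differed by sex in opposite senses in the 2 lines, with median differences of 0.86 (neo-in; 0 genes called, 12 higher over the list alone, camera adjusted p = 4.98e-13, and adjusted p = 0.299 with an estimated correlation) and -0.87 (neo-out; 9 lower over the list alone, camera adjusted p = 9.9e-08, and adjusted p = 0.385 with an estimated correlation). Interferon-stimulated genes differed by sex in neo-in as a list (median -1.05; 0 of 18 called, 16 lower over the list alone, camera adjusted p = 2.59e-13, and adjusted p = 0.299 with an estimated correlation).

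In the cortex, Htt fell from 219 ± 7.9 to 170 ± 4.53 CPM in the neo-in line (-0.37 ± 0.03, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 1.79e-09, 77.5% of wild type, n = 8 and 8) and from 225 ± 12.7 to 181 ± 4.43 in the neo-out line (-0.31 ± 0.03, adjusted p = 5.85e-08, 80.8%, n = 8 and 8). All 8 Het values lay below all wild-type values in each line (exact p = 0.000155). Neo-out Het mice had 0.10 log2 more Htt than neo-in Het mice (exact p = 0.000622, adjusted 0.00124; edgeR adjusted p = 0.0936), and the 2 Het effects did not differ (0.06 ± 0.04, adjusted p = 0.996). The wild-type groups were 0.04 apart (exact permutation p = 0.312).

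Which cortical genes changed in neo-in Het mice? Of 17444 tested, 76 rose and 222 fell, 8 against 8 libraries (edgeR quasi-likelihood, Benjamini-Hochberg). Abhd1 rose from 1.6 to 5.17 CPM (+1.70 ± 0.11, adjusted p = 2.5e-11), Enpp6 by 0.62 ± 0.10 (adjusted p = 0.000592) and Prdm8 by 0.45 ± 0.06 (adjusted p = 9.49e-05). Ptprv fell by 1.51 ± 0.23 (adjusted p = 0.000273), Cd4 by 1.44 ± 0.28, Slc4a11 by 0.86 ± 0.15 and Aldh1a3 by 0.85 ± 0.14. Striatum-enriched genes were among the decreases: Rgs9 fell from 25.6 ± 17.4 to 11.2 ± 0.937 CPM (-1.04 ± 0.17, adjusted p = 0.000869) and Penk from 63.9 ± 43.9 to 29 ± 4.53 (adjusted p = 0.00487). Beside these genes, Drd2 stood at 8.72, 4.35 and 7.26 CPM in wild-type females 1, 2 and 3 of this line and at no more than 3.04 CPM in the other 29 cortex libraries. Without the 5 libraries high in Drd2 or Ttr the count was 65, of which 57 were among the 298. That fit kept 1 neo-in wild-type female (female 4), so it leans on a single library. Leaving out Het female 3 or Het male 4 alone gave 198 and 195.

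**Figure D3:**
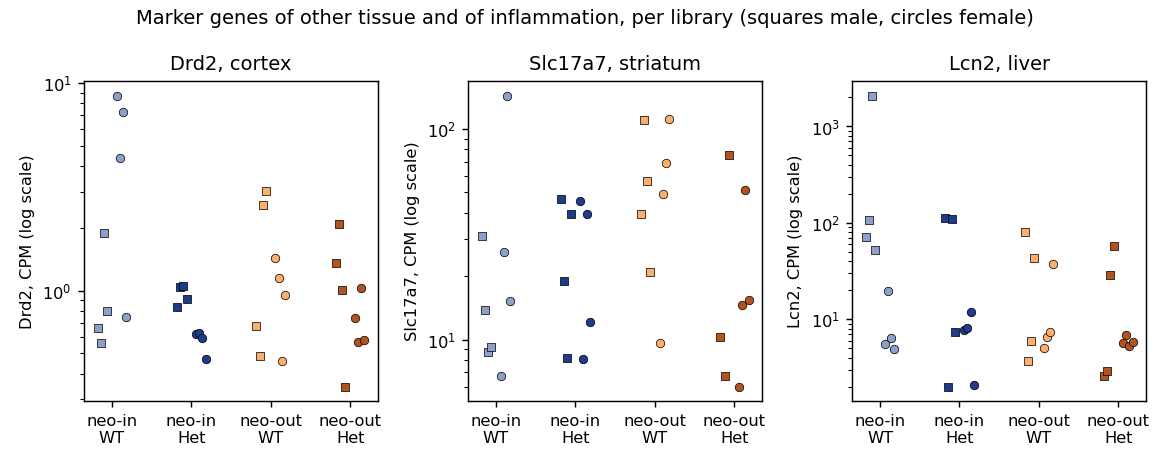
Drd2 in cortex, Slc17a7 in striatum and Lcn2 in liver, in CPM on a log scale, for each library by line and genotype. The 3 highest Drd2 values, 8.72, 7.26 and 4.35 CPM, are wild-type females of the neo-in line.

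Of 34 shared MSN genes 13 fell in neo-in cortex (26 adjusted over the list alone, median -0.21, camera adjusted p = 4.6e-23, and adjusted p = 0.00297 with an estimated correlation), including Ppp1r1b, which encodes DARPP-32 (-0.62 ± 0.09), and Ddit4l (-0.48 ± 0.06, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 6.32e-06). Indirect-pathway markers fell in 2 of 8 (5 adjusted over the list alone, camera adjusted p = 0.00718, and adjusted p = 0.381 with an estimated correlation) and direct-pathway markers in 3 of 8 (4 adjusted over the list alone, camera adjusted p = 0.0256, and adjusted p = 0.532 with an estimated correlation). Drd1 was called at -0.53 ± 0.13 and stood at +0.04 without the 5 libraries. Over the MSN lists, without Drd2 and Adora2a, the 18 genes called lower had a median of -0.40. Their median was -0.30 with the Drd2 and Adora2a level as a covariate and -0.18 without the 5 libraries. Neurotrophin and activity genes of cortex fell in 7 of 12, 7 adjusted over the list alone (camera adjusted p = 3.82e-09, and adjusted p = 0.00261 with an estimated correlation), among them Nptx2, a synaptic pentraxin (-0.49 ± 0.07, adjusted p = 6.9e-05), the peptide gene Crh (-0.57 ± 0.10) and Scg2 (-0.38 ± 0.06). Astrocyte markers had 3 of 15 lower (5 lower and 1 higher adjusted over the list alone), with Slc4a4 at -0.19 (camera adjusted p = 0.00138, and adjusted p = 0.414 with an estimated correlation). Immediate early genes, as a mean of both sexes, had 2 of 16 lower (4 adjusted over the list alone), with Npas4 at -0.58 ± 0.13. That list had a camera adjusted p of 0.001, and adjusted p = 0.595 with an estimated correlation. Fos stood at 34.1 to 60.1 CPM in Het females and 18.1 to 37.5 in wild-type females. In males it stood at 13.1 to 20.5 in Het and 27.9 to 51.6 in wild type. None of 21 beta protocadherins was called (camera adjusted p = 0.897), and 7 of 27 lists passed camera, 2 with an estimated correlation.

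In neo-out Het cortex 145 genes rose and 349 fell, 8 against 8 libraries (edgeR quasi-likelihood, Benjamini-Hochberg). The count of 494 became 115 with the clock covariate (median change 0.248 to 0.265, error 0.0562 to 0.0825) and 819 with voom, and the cortical clock score itself was 0.42 in Het and 0.13 in wild-type mice of this line. Abhd1 rose from 1.54 to 5.33 CPM (+1.81 ± 0.11, adjusted p = 6.75e-12), Abca8a by 0.46 ± 0.05 (adjusted p = 7.39e-07), Chdh by 0.52 ± 0.09 and Enpp6 by 0.53 ± 0.10. Gpr153, an orphan receptor, fell from 29.8 ± 3.34 to 15.5 ± 2.32 CPM (-0.94 ± 0.08, adjusted p = 7.39e-09), Slc4a11 by 0.99 ± 0.17, Plk5 by 0.91 ± 0.13, Adam33 by 0.80 ± 0.11 and Ddit4l by 0.65 ± 0.06 (adjusted p = 1.91e-08). Shared MSN genes fell in 8 of 34 (13 adjusted over the list alone, median -0.11, camera adjusted p = 4.9e-07, and adjusted p = 0.251 with an estimated correlation), Ppp1r1b by 0.48 ± 0.09 and Scn4b by 0.37 ± 0.07. Tested between the lines, the shared MSN list differed by camera (adjusted p = 7.7e-05) but had adjusted p = 0.381 with an estimated correlation. Neurotrophin and activity genes fell in 4 of 12 (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.44e-06, and adjusted p = 0.00637 with an estimated correlation), with Nptx2 at -0.57 ± 0.07 (adjusted p = 5.62e-06) and Sorcs3 at -0.39 ± 0.07.

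Cholesterol synthesis genes fell in the neo-out cortex, 7 of 21 called and 16 adjusted over the list alone (median -0.16, camera adjusted p = 7.43e-14, and adjusted p = 0.0373 with an estimated correlation). Insig1 fell by 0.42 ± 0.06, Stard4 by 0.27 and Fdft1 by 0.17 (edgeR quasi-likelihood). In the neo-in cortex 0 of the 21 were called (camera adjusted p = 0.88). Neo-out wild-type cortex was itself higher on this list than neo-in wild type, as given below. Of cortical excitatory markers 4 of 20 fell (4 lower and 1 higher adjusted over the list alone), with Lamp5 at -0.52 ± 0.07, and the list was not called (camera adjusted p = 0.0964). Astrocyte markers had 2 of 15 lower (6 lower and 1 higher adjusted over the list alone), with Slc4a4 at -0.20 (camera adjusted p = 4.87e-05, and adjusted p = 0.294 with an estimated correlation).

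The direct test between the lines called 0 of 17444 cortical genes by edgeR quasi-likelihood; 906 had an unadjusted p below 0.05, DESeq2 called 7 and voom 1. As a list, cholesterol synthesis differed between the lines (median -0.16, 0 genes called, 6 lower over the list alone). Camera gave it an adjusted p of 4.3e-15, and adjusted p = 0.0288 with an estimated correlation. Neo-out wild-type cortex was itself higher on this list than neo-in, so the difference does not show which genotype carries it. The lines shared 29 genes called higher (0.632 expected) and 111 called lower (4.44 expected), with 0 in opposite directions, and 96.3% of the neo-in calls had the same sign in neo-out. The mean change over the 1186 genes called with both lines together was 0.223 in neo-in and 0.244 in neo-out, a ratio of 1.09 ± 0.0728 (permutation p = 0.208). Removal of 1 library gave 0 to 3 called genes, the 3 without neo-in Het male 4.

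Between wild-type cortices, 308 genes differed, 133 of them lower in neo-out, 8 against 8 libraries (edgeR quasi-likelihood, Benjamini-Hochberg). Cholesterol synthesis genes were again higher in neo-out wild type, 12 of 21 called and 19 adjusted over the list alone (median 0.23, camera adjusted p = 1.3e-24, and adjusted p = 0.00519 with an estimated correlation). The kinase gene Nuak1 was higher (+0.57 ± 0.07, adjusted p = 1.47e-05), as were Cbfa2t3 (+0.70) and Trib2 (+0.56); Usp2 (-0.41 ± 0.04, adjusted p = 3.41e-08), Flrt2 (-0.48 ± 0.05, adjusted p = 2.82e-07) and Dbp (-0.59) were lower. A fit without the 5 libraries high in Drd2 or Ttr kept 1 neo-in wild-type female, female 4. The count was 166 and 193 without neo-in wild-type female 1 or 3, 203 and 154 without neo-out female 3 or 4, and 478 without neo-in female 2. It was 108 with the clock covariate (median change 0.279 to 0.362, error 0.0627 to 0.121) and 65 without the 5 libraries high in Drd2 or Ttr.

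Genotype by sex called 28 cortical genes in the neo-in line (25 higher and 3 lower) and 10 in the neo-out line (2 and 8), by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Activity genes led both. In the neo-in line they were Arc (2.57 ± 0.38, adjusted p = 0.00129), Fos (1.86 ± 0.27, adjusted p = 0.00119), Egr2 (2.72 ± 0.42, adjusted p = 0.00164) and Nr4a1 (1.72 ± 0.24, adjusted p = 0.00119). In the neo-out line Fos (-1.53 ± 0.27, adjusted p = 0.0135) and Dusp1 (-1.45 ± 0.24) had the other sign. Immediate early genes as a list had 8 of 16 called in neo-in (13 adjusted over the list alone, median 1.32, camera adjusted p = 5.66e-36, and adjusted p = 0.00403 with an estimated correlation). In neo-out 2 were called (9 adjusted over the list alone, camera adjusted p = 3.44e-19, and adjusted p = 0.0409 with an estimated correlation). Pde10a differed by sex in neo-in (-1.44 ± 0.26, adjusted p = 0.012); it is an MSN gene, and the Drd2-rich wild-type libraries were all female. The neo-in count was 10 without wild-type female 1, 12 without wild-type female 3, 81 without wild-type female 2 and 89 without wild-type female 4. It was 0 with the striatal share (Drd2 and Adora2a) as a covariate, 0 with libraries of that line alone and 5 without the 5 libraries high in Drd2 or Ttr. That fit kept 1 neo-in wild-type female, female 4. The neo-out count lay between 3 (without Het male 3) and 18 (without wild-type male 1).

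Htt stood at lower CPM in liver than in brain and fell further there. It went from 37.7 ± 5.27 to 25.3 ± 2.48 CPM in neo-in (-0.57 ± 0.07, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.000154, 67.4% of wild type, n = 8 and 8) and from 37 ± 3.87 to 26.3 ± 2.73 in neo-out (-0.49 ± 0.07, adjusted p = 0.000661, 71.1%, n = 8 and 8), with exact p of 0.000155 and 0.000311. With the clock covariate the neo-out decrease was smaller and no longer called. Neither the Het groups (0.06, exact permutation p = 0.449) nor the wild-type groups (-0.02, p = 0.837) differed between lines, and the difference of effects was 0.08 ± 0.10 (adjusted p = 0.809). Over both lines the Htt decrease was larger in liver than in striatum by 0.20 log2 (permutation p = 0.00323, adjusted 0.0145 over 9 comparisons) and than in cortex by 0.19 (p = 0.00193, adjusted 0.0145), while cortex and striatum did not differ (-0.02, p = 0.622).

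In the neo-in liver 70 genes rose and 19 fell of 15208, 8 against 8 libraries (edgeR quasi-likelihood, Benjamini-Hochberg). Abhd1 was the clearest, from 1.98 ± 0.214 to 22 ± 3.73 CPM (+3.47 ± 0.11, adjusted p = 6.26e-19). The lipid genes Pnpla3 (+2.33 ± 0.49, adjusted p = 0.0313; 1.44 ± 1.45 to 6.69 ± 6.51 CPM) and Acss2, an acetyl-CoA synthetase (147 ± 51.2 to 439 ± 265 CPM, adjusted p = 0.0228), rose, and the amino acid transporter Slc7a5 fell (-0.63 ± 0.13, adjusted p = 0.0278). Of 17 lipogenesis genes 1 was called and 12 when adjusted over the list alone, all higher (camera adjusted p = 1.31e-07, and adjusted p = 0.385 with an estimated correlation). Het male 2 had a lipogenesis score of 8.52, against 7.26 to 7.44 in the other Het males, and without it Pnpla3 was at +1.59 (adjusted p = 0.205) and Acss2 at +1.10 (adjusted p = 0.108). PPAR alpha targets were lower (median -0.28, 0 of 19 called, 5 lower and 1 higher over the list alone, camera adjusted p = 0.000282, and adjusted p = 0.605 with an estimated correlation). Acute phase genes were lower as well (median -0.50, 0 of 19 called, 0 over the list alone, camera adjusted p = 3.72e-05, and adjusted p = 0.605 with an estimated correlation). Beside the acute phase list, wild-type male 3 held 2.09e+03 CPM of Lcn2, against at most 112 in each other liver. The count of 89 became 314 with DESeq2, 359 with voom, 10 and 11 with FPKM (pseudocount 0.1 and 1), 8 with unfiltered FPKM and 3 with libraries of that line alone. It also moved widely with single animals. It was 7 without Het male 2, 10 and 12 without Het females 3 and 4 and 11 without Het male 4. It was 18 and 19 without wild-type female 2 or male 1, 172 without wild-type male 3, and 247 and 313 without Het males 1 and 3.

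In the neo-out liver 46 genes rose and 32 fell, 8 against 8 libraries (edgeR quasi-likelihood, Benjamini-Hochberg). Abhd1 rose from 1.52 ± 0.354 to 21.3 ± 2.53 CPM (+3.82 ± 0.12, adjusted p = 9.04e-20). Several other large changes were in clock genes. Dbp rose from 3.18 ± 2.2 to 43.8 ± 29.2 CPM (+3.55 ± 0.47, adjusted p = 0.000173), Per3 from 4.27 ± 1.96 to 20.4 ± 11.9 (+2.13 ± 0.31, adjusted p = 0.000428) and Tef by 1.30 ± 0.20. Npas2 fell by 1.98 ± 0.40 (adjusted p = 0.0155). Of 16 clock genes 8 rose and 1 fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.000107), but adjusted p = 0.0982 with an estimated correlation. Prox1, a hepatocyte transcription factor, fell by 0.83 ± 0.13 (adjusted p = 0.00167), and Clpx, a mitochondrial protease subunit, by 0.93 ± 0.17. Immediate early genes were higher (1 of 13 called, Egr1 at +1.53 ± 0.35, and 8 adjusted over the list alone, camera adjusted p = 1.76e-05, and adjusted p = 0.386 with an estimated correlation). Het male 3 held 75.7 CPM of Fos, against 1.3 to 18.6 in the other Het livers of the line, and without it Egr1 was at +1.23 (adjusted p = 0.152). Heat shock genes were higher too (0 of 15 called, 7 adjusted over the list alone, camera adjusted p = 1.28e-05, and adjusted p = 0.461 with an estimated correlation). Of 28 liver lists 10 passed camera in neo-in and 9 in neo-out, and 0 passed with an estimated correlation in either line. The count was 34 without Het male 3, 38 without Het female 1, 130 without neo-in wild-type male 3 and 134 without Het male 2, and 6 with the clock covariate (median change 0.654 to 0.532, error 0.131 to 0.17).

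The 2 lines differed in their liver response in 132 genes (53 higher and 79 lower in neo-out; edgeR quasi-likelihood, Benjamini-Hochberg). Of 16 clock genes 6 were higher and 2 lower (10 and 5 adjusted over the list alone, camera adjusted p = 0.000112, and adjusted p = 0.0982 with an estimated correlation), among them Dbp (4.34 ± 0.62, adjusted p = 0.00109), Per3 (2.65 ± 0.41, adjusted p = 0.00259), Tef (1.71 ± 0.28) and Nr1d2 (1.03 ± 0.17). Outside the list, Clpx (-1.38 ± 0.23), Asap2 (-1.84 ± 0.31, adjusted p = 0.00389) and Blcap (-0.70 ± 0.10, adjusted p = 0.00108) were lower. The lines shared 1 gene called higher and 1 called lower, Abhd1 and Htt, and over all genes the 2 responses were unrelated (r = -0.01). With both lines together 4 genes rose and 7 fell. That count of 11 ranged from 7 to 64 with 1 library left out and was 108 with the clock covariate. The count of the line difference was 58 without neo-in Het male 4, 59 without neo-in Het male 2, 281 without neo-in Het male 3 and 327 without neo-in wild-type male 3, and 2 with the clock covariate (median change 0.929 to 0.689, error 0.207 to 0.241).

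Wild-type livers of the 2 lines differed far more than Het from wild type, with 758 genes higher and 691 lower in neo-out, 8 against 8 libraries (edgeR quasi-likelihood, Benjamini-Hochberg). Dbp was at 3.18 ± 2.2 CPM in neo-out and 68.5 ± 30.9 in neo-in wild type (-4.40 ± 0.49, adjusted p = 2.91e-06), Per3 was lower by 3.25 ± 0.31 (adjusted p = 6.22e-07), and Npas2 was higher by 4.05 ± 0.50 (adjusted p = 1.23e-05). Of 16 clock genes 5 were higher and 9 lower (5 and 10 adjusted over the list alone, camera adjusted p = 0.00523, and adjusted p = 0.336 with an estimated correlation). Stellate cell markers were higher in 6 of 12 (7 adjusted over the list alone, camera adjusted p = 2.65e-06, and adjusted p = 0.336 with an estimated correlation), and xenobiotic genes in 6 of 18 with 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0063, and adjusted p = 0.741 with an estimated correlation). A clock score, the mean of Dbp, Per3, Tef, Ciart and Per2 less the mean of Arntl, Npas2, Clock and Cry1, was 3.51 ± 1.22 in neo-in and -1.77 ± 0.92 in neo-out wild-type livers, and 2.02 ± 1.82 and 1.59 ± 1.37 in the Het livers, n = 8 each. With the clock covariate, which did not overlap between the 2 wild-type groups, the count of 1449 became 12, as the median change of these genes fell from 0.449 to 0.3 and its error rose from 0.109 to 0.199.

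**Figure D4:**
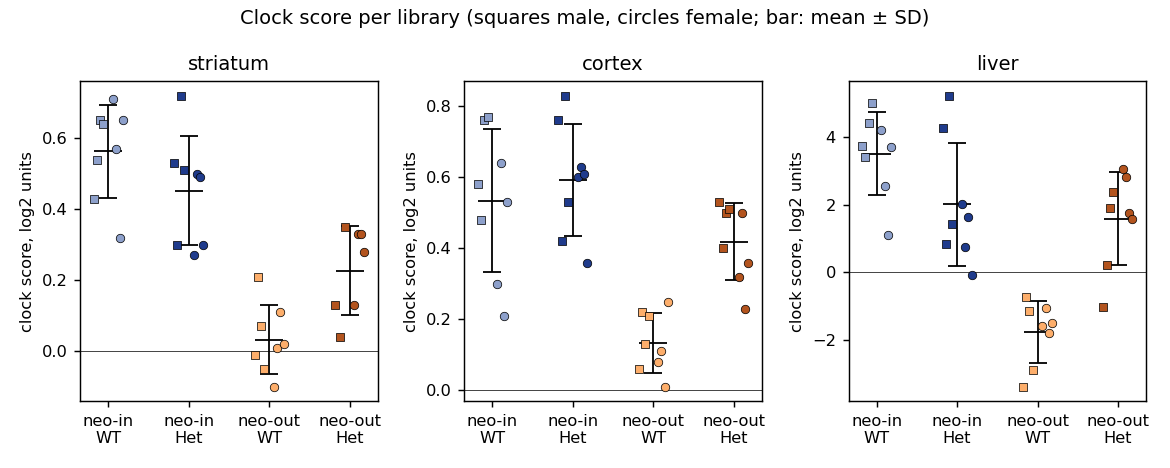
Clock score (log2 CPM) of each library by tissue, line and genotype. Neo-out wild-type livers lie lowest (-1.77 ± 0.92) and neo-in wild-type livers highest (3.51 ± 1.22).

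Genotype by sex called 1 liver gene in neo-in, Spc25 (-1.97 ± 0.30, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.00658), and 21 in neo-out (9 higher, 12 lower), led by Hhex (-2.79 ± 0.36, adjusted p = 0.000324), Zbtb16 (3.40 ± 0.52) and Egr1 (3.86 ± 0.71). The neo-out count ranged from 3 (without wild-type female 3) to 34 (without Het male 2 or 3), and the neo-in count from 1 to 5 (without Het male 3).

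**Figure D5:**
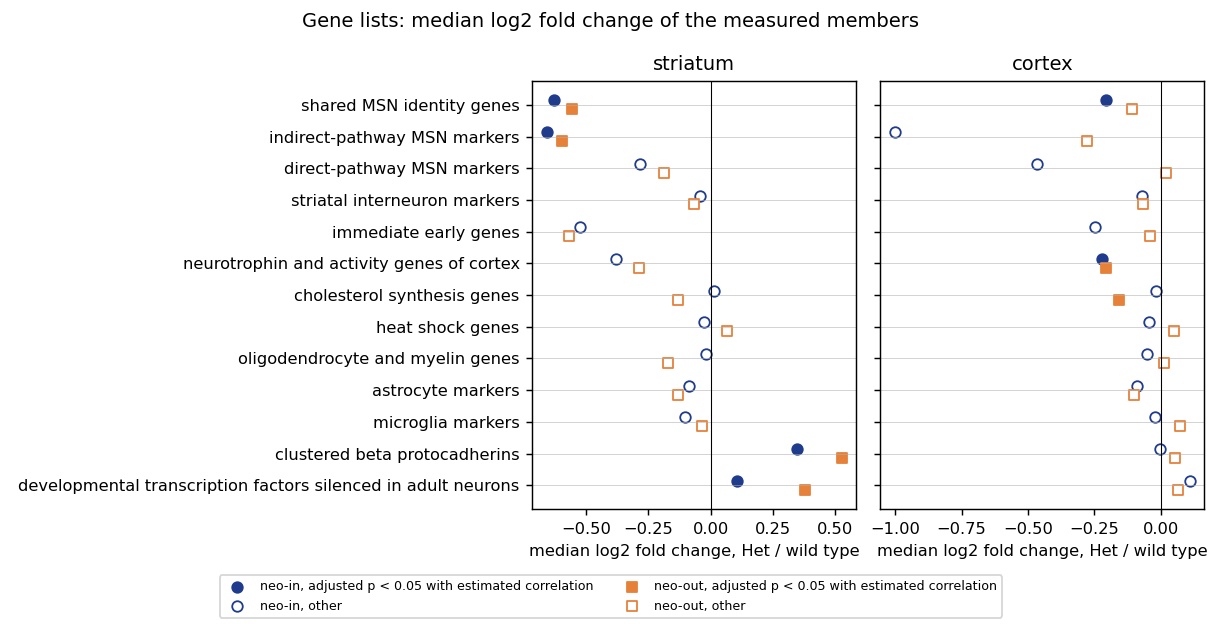
Median log2 fold change of 13 gene lists, Het against wild type, in striatum and cortex of each line, filled where camera with an estimated correlation passed 0.05. Shared MSN genes (-0.63 in neo-in, -0.56 in neo-out) and indirect-pathway markers are lower in striatum, and beta protocadherins are higher there (0.34 and 0.53).

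Which changes were common to the tissues? Abhd1 and Htt were the only 2 genes called in all 3 tissues and both lines. Abhd1 (ENSMUSG00000006638, chromosome 5, start 30950066, end 30955091, plus strand), which encodes an alpha/beta hydrolase domain protein, lies 3.81 Mb from Htt and overlaps Preb on the other strand. Its rise was larger in liver than in striatum by 2.05 ± 0.15 log2 in neo-in and 2.41 ± 0.15 in neo-out. Striatum and cortex of the neo-in line shared 46 genes called higher (6.82 expected) and 134 called lower (23.4 expected), with 5 in opposite directions; the neo-out line shared 79 (13.2 expected), 158 (30.9 expected) and 9. Striatum and liver shared 5 higher (5.64 expected) and 6 lower (1.79 expected) in neo-in, with 9 in opposite directions, and 8 (4.09 expected), 6 (2.63 expected) and 6 in neo-out. The expected counts take the tissues as independent, although they came from the same animals.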

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

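The tests of an allele effect on the liver clock and of the Abhd1 response in liver against striatum were chosen after the results were seen, as were the alternatives without marker-rich libraries and with a clock or striatal share covariate. The other tests below were written before their own outcome was seen. Those on the liver line difference, the cortical MSN genes and Abhd1 were still written after these patterns had been found. Results are listed here when 1 library lay far from the other 3 of its group (a gap beyond Dixon's 95% critical share of the range) or when an effect differed between lines, sexes or tissues by a test of the difference.

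Of 168 groups tested 16 held a library far from its others, and about 1 in 20 groups would by chance. Log2 Htt was 7.27 in striatum of neo-out wild-type female 3 (others 7.61 to 7.66), 7.36 in cortex of neo-in Het female 1 (7.44 to 7.45) and 5.11 in liver of neo-in wild-type male 4 (5.41 to 5.47). Totals of 43.1 M in striatum and 46.3 M in liver of neo-in wild-type female 1 (others 35.47 to 36.26 and 40.63 to 41.27) and 68.4 M in liver of neo-out wild-type male 3 (37.71 to 41.66) stood above their groups. Choroid plexus scores were 2.83, 1.86 and 3.81 in cortex of neo-in Het female 3, neo-in Het male 1 and neo-out wild-type female 1, against -0.36 to -0.12, 0.02 to 0.32 and -0.11 to 0.09 in the others. Cortex of neo-in Het male 2 had a shared MSN score of 6.00 (5.94 to 5.95) and an immediate early gene score of 4.10 (4.55 to 4.57), neo-in Het female 4 a clock score of 0.36 (0.60 to 0.63) and neo-out wild-type female 3 a cholesterol score of 5.73 (5.63 to 5.64). In liver, neo-in wild-type male 3 had an acute phase score of 11.22 (others from 8.56 upward by less than 1), neo-in Het male 2 a lipogenesis score of 8.52 (7.26 to 7.44) and neo-out Het female 2 a clock list score of 4.43 (4.27 to 4.30).

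Between the lines, by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, the Het effect differed for 1 striatal gene, Nr1d1 (0.62), and 132 liver genes, led by Dbp (4.34), Per3 (2.65), Tef (1.71), Nr1d2 (1.03), Narf (0.79), Asap2 (-1.84), Loxl4 (-1.61), Plat (-1.55), Clpx (-1.38) and Blcap (-0.70). The cortical cholesterol list differed between the lines with a median of -0.16, and neo-out wild-type cortex was itself higher on it than neo-in wild type. By sex, striatum had 1 gene in each line (Pvr 0.58 in neo-in, Zbtb16 2.28 in neo-out). Cortex had 28 in neo-in, led by Egr2 (2.72), Arc (2.57), Fos (1.86), Nr4a1 (1.72), Dusp1 (1.54), A230087F16Rik (-1.55), Pde10a (-1.44) and Kcnj2 (-0.87), and 10 in neo-out, led by Fos (-1.53), Dusp1 (-1.45), Adamts1 (-1.26), Fbn1 (-1.17), Phf13 (-0.70), Lrfn2 (0.97) and Iqgap2 (0.65). The immediate early list had medians of 1.32 and -0.76 in these 2 tests. Liver had 1 gene in neo-in (Spc25, -1.97) and 21 in neo-out, led by Egr1 (3.86), Zbtb16 (3.40), Slc25a34 (1.70), Pfkfb1 (1.35), Fam214a (1.26), Hhex (-2.79), Uckl1os (-1.89), Il1a (-1.68), Jade3 (-1.10) and Zfp568 (-0.76). The Htt decrease over both lines was larger in liver than in striatum (-0.20, permutation p = 0.00323) and than in cortex (-0.19, permutation p = 0.00193). Within a line no adjusted p passed 0.05. Liver less striatum was -0.24 in neo-out (exact permutation p = 0.0212, adjusted 0.0524) and -0.17 in neo-in (exact permutation p = 0.082, adjusted 0.123). Liver less cortex was -0.20 in neo-in (exact permutation p = 0.0233, adjusted 0.0524) and -0.19 in neo-out (exact permutation p = 0.0396, adjusted 0.0713).

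Whether chance assignment could give the counts was tested with 100 splits of the groups, the real 1 among them. For Het against wild type the real count was reached by no other split in striatum (3496 in neo-in, highest other 394; 3216 in neo-out, 1250; 5750 over both lines, 4), cortex (298, 3; 494, 5; 1186, 2) or either line's liver (89, 32; 78, 4), and over both lines in liver 11 was reached by 1 other (2 splits in all; highest other 39). Genotype by sex in cortex was reached by the real split alone (28, highest other 10; 10, highest other 1), in neo-out liver by 2 (21; 26) and in neo-in striatum by 3 (1; 6). Chance was not excluded for genotype by sex in neo-out striatum (1 gene; 10 splits as large, highest other 884) and neo-in liver (1 gene; 8 splits, highest other 5), nor for the line difference in striatum (1 gene; 5 splits, highest other 1803). In cortex the line difference had 0 genes, which all 100 splits reach whatever they hold (highest other 1), so that test decides nothing. The line difference in liver was reached by the real split alone (132, highest other 90), as were the wild-type comparisons of cortex (308, 12) and liver (1449, 371), while in striatum 87 was reached by 2 (highest other 620). Splits of 884 and 1803 genes against a real 1, 620 against 87 and 39 against 11 point to a structure of the samples, which was not identified. In the genotype splits (884 and 39) the real genotype effect stays in the data and may add to the counts, which was not tested. The line splits (1803 and 620) keep genotype. For genotype by sex and the line difference, a split also turns a real genotype or line effect into spread within groups. That may lower the counts of the other splits. A count reached by the real split alone therefore does not exclude chance for these contrasts.

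The liver difference between the lines has a clock pattern. If animals were collected at different hours, or had shifted clocks, the slope of each gene on the clock score of the same animals' brain, within groups, should give the sign of its line difference; it did for 88.6% of the 132 genes (109 of 124 outside the clock list), although the median predicted size was 19.5% of the observed. With that score as a covariate 2 genes stayed called, with the median absolute change falling from 0.929 to 0.689 and its error rising from 0.207 to 0.241, so part of the loss came from a wider error. An action of the allele or cassette on the liver clock as the whole cause is argued against by 14 clock genes called between the wild-type groups, which carry neither. The inflamed wild-type liver is argued against by 327 genes called without it; collection hour was not stated, so hour and shifted clocks may each remain.

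Lower MSN genes in neo-in Het cortex could come from striatal tissue in 3 wild-type female cortices. With the Drd2 and Adora2a level as a covariate the called MSN genes kept 74.2% of their median change (-0.40 to -0.30, error 0.0787 to 0.0802). That share lies between the bounds written before it was seen, and 8 of the 18 genes stayed called. Without the 5 marker-rich libraries the median was -0.18 (43.4%), but that fit kept 1 neo-in wild-type female (female 4). How much of the neo-in decrease is striatal tissue therefore cannot be told apart here. In the neo-out line the same covariate left 106% of the median and all 9 genes called, which argues against striatal tissue there. With the covariate 9 shared MSN genes were called lower in neo-in, 1 of them (Rgs4) newly, so an effect of the allele on cortical neurons stays open.

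Abhd1 rose in every tissue of both lines. A joint rise of its neighbours is argued against by a median of -0.045 in liver for Khk (0.16), Cgref1 (-0.23) and Preb (-0.05), where Abhd1 rose by over 3. These totals cannot show whether transcripts extending from a neighbour were counted as Abhd1, and whether the libraries keep strand was not stated. The rise was larger in liver than in striatum by 2.05 ± 0.15 and 2.41 ± 0.15, although far more genes were called in striatum. That comparison was chosen after the values were seen, and a single gene may respond most in any tissue. It therefore does not decide on a response to mutant huntingtin. Genes within 20 Mb of Htt were called in cortex over both lines 1.72 times as often as elsewhere (11.6% of 251 against 6.72% of 17191, Fisher exact p = 0.00498). That value lies between the bounds written before it was seen. The ratio was 2.15 in neo-in cortex (Fisher exact p = 0.0411) and 0.989 in neo-out cortex, in striatum 1.12 over both lines (Fisher exact p = 0.185), 1.23 in neo-in (p = 0.0727) and 1.04 in neo-out (p = 0.748), and in liver 9.1 (1 gene near Htt called, p = 0.116), 0 (p = 0.634) and 1.97 (2 genes, p = 0.275). No genotypes were analysed here. A strain segment carried with the knock-in allele and an effect of the allele on a neighbour 3.81 Mb away both stay open. A response to mutant huntingtin and transcripts that extend into Abhd1 stay open as well.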

How the results depend on the processing

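The alternatives without marker-rich libraries, with the clock score, with the library number term and with the striatal share were chosen after the results were seen; all others were set before the data were examined. A result is given here where its count moved by more than 1.5-fold, its call changed or its sign reversed, and in each case the cause was not tested unless said. RLE size factors moved no count beyond that bound, and the liver effect ratio gave no value, with 11 genes where 20 were needed. Without marker-rich libraries the cortex fit kept 1 neo-in wild-type female, so its counts that involve the neo-in line lean on that library. At a depth of 31.02 M or more the smallest simulated change was recovered in 42% (liver) to 68% (cortex) of genes for Het against wild type, and in 16% (liver) to 54% (cortex) for the line difference.

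For Het against wild type in striatum 1 count moved beyond that bound, neo-out with the clock covariate, from 3216 to 1370 genes, of which 1236 were among the 3216. The balance of directions moved with FPKM (0.1): to 2834 up and 1335 down from 1592 and 1904 in neo-in, to 2426 and 1276 from 1569 and 1647 in neo-out, and to 4557 and 2005 from 2945 and 2805 over both lines. In cortex the neo-in count of 298 became 172 with the clock covariate, 173 with unfiltered FPKM, 124 with libraries of that line alone and 65 without marker-rich libraries, and the neo-out count of 494 became 115 with the clock covariate and 819 with voom. Both lines together, 1186 genes, became 688 without marker-rich libraries, 603 of them among the 1186. In liver the neo-in count of 89 became 314 (DESeq2), 359 (voom), 10 and 11 (FPKM, pseudocount 0.1 and 1), 8 (unfiltered FPKM), 3 (line alone), 56 (library number), 43 (no low-count filter) and 172 (without the marker-rich library). The neo-out count of 78 became 6 (clock), 166 (DESeq2), 319 (voom), 48 (FPKM, pseudocount 1), 29 (unfiltered FPKM) and 130 (without the marker-rich library). Both lines in liver, 11 genes, became 108 (clock), 122 (DESeq2), 177 (voom), 7 (FPKM, pseudocount 1) and 17 (additive sex).

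The line difference in striatum, 1 gene, became 0 with the clock covariate and 3 with DESeq2, and in cortex 0 became 7 with DESeq2 and 1 with voom. In liver 132 became 2 (clock), 320 (DESeq2), 553 (voom), 81 and 69 (FPKM, 0.1 and 1), 28 (unfiltered FPKM) and 327 (without the marker-rich library). Wild-type striatum, 87 genes, became 0 (clock), 194 (DESeq2), 284 (voom), 55 and 55 (FPKM, 0.1 and 1), 46 (unfiltered FPKM) and 15 (without marker-rich libraries). Wild-type cortex, 308, became 108 (clock), 491 (DESeq2), 179 (unfiltered FPKM), 162 (striatal share) and 65 (without marker-rich libraries), and wild-type liver, 1449, became 12 (clock) and 2204 (voom). The clock covariate did not overlap between the wild-type groups of the lines in any tissue (for liver -0.48 to 1.43 and -1.62 to -0.69) and widened the errors of those comparisons, so a lost call there does not show that the clock accounts for the change.

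For genotype by sex, neo-in cortex, 28 genes, became 83 (DESeq2), 14 (voom), 0 (line alone), 0 (striatal share) and 5 (without marker-rich libraries), and neo-out cortex, 10, became 36 (DESeq2), 29 (voom), 3 (unfiltered FPKM) and 19 (line alone). Neo-in liver, 1, became 32 (DESeq2), 2 (voom), 0 (line alone) and 3 (library number), and neo-out liver, 21, became 86 (DESeq2) and 85 (voom). Neo-in striatum, 1, became 3 (DESeq2), 18 (voom) and 0 with FPKM (0.1 and 1), the line alone, the library number term, no filter and without marker-rich libraries. Neo-out striatum, 1, became 93 (DESeq2), 193 (voom), 2 and 2 (FPKM, 0.1 and 1), 0 (legacy quasi-likelihood), 29 (line alone), 3 (no filter) and 3 (without marker-rich libraries).

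With replicate number as a block, as though libraries of the same number were paired, Het against wild type gave 179 (neo-in cortex), 267 (neo-out cortex), 230 (neo-in liver), 34 (neo-out liver) and 94 (liver, both lines), wild-type cortex 199, and genotype by sex 8 and 3 (cortex), 3 (neo-in liver), 0 and 15 (striatum, neo-in and neo-out). The numbers do not mark pairs: the mean correlation of same-number residuals was -0.0389 in cortex, 0.0358 in liver and 0.0446 in striatum.

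Htt stayed lower in Het mice under every alternative. In neo-out liver the clock covariate ended its call (-0.49 to -0.37, adjusted p = 0.218). The Het-against-Het difference in cortex, 0.10 (edgeR adjusted p = 0.0936), was called with DESeq2 (0.10, adjusted p = 0.0376), voom (0.10, adjusted p = 0.0306) and the striatal share (0.10, adjusted p = 0.0489), and in liver it was -0.03 with the clock covariate, not called. The wild-type difference in striatum, -0.01, was never called and turned positive with the clock covariate (0.11), FPKM (0.01 in each of 3 settings), voom (0.02) and without marker-rich libraries (0.03). The effect ratio, 1.02 in striatum and 1.09 in cortex, was 0.828 and 0.689 over genes called in neo-in alone and 1.28 and 1.73 over genes called in neo-out alone, which follows from choosing genes by the line in the denominator or numerator.

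With 1 library left out at a time, Het against wild type ranged over 3073 to 3625 (striatum neo-in), 2480 to 3375 (neo-out) and 5164 to 5873 (both), 195 to 318, 335 to 510 and 1007 to 1198 in cortex, and 7 to 313, 34 to 134 and 7 to 64 in liver. The line difference ranged over 1 to 1, 0 to 3 and 58 to 327 in striatum, cortex and liver, and the wild-type comparison over 46 to 139, 154 to 478 and 1167 to 1892. Genotype by sex ranged over 0 to 24 and 0 to 13 in striatum (neo-in and neo-out), 10 to 89 and 3 to 18 in cortex, and 1 to 5 and 3 to 34 in liver. The Htt change stayed between -0.41 and -0.35 (neo-in) and -0.27 and -0.20 (neo-out) in striatum, -0.37 and -0.35, and -0.34 and -0.29 in cortex, and -0.60 and -0.53, and -0.53 and -0.46 in liver. The other Htt differences ranged over 0.12 to 0.19, 0.03 to 0.07 and 0.04 to 0.12 between the lines (striatum, cortex, liver), 0.12 to 0.18, 0.09 to 0.10 and 0.01 to 0.09 between Het groups, and -0.03 to 0.03, 0.03 to 0.07 and -0.06 to 0.02 between wild-type groups. By sex they ranged over 0.10 to 0.23 and 0.02 to 0.15 in striatum, 0.11 to 0.15 and -0.08 to 0.01 in cortex, and 0.17 to 0.33 and 0.22 to 0.35 in liver. Effect ratios ranged over 0.984 to 1.04 and 1.06 to 1.12.

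Of the named gene results, 132 lost their call with the clock covariate, 78 with unfiltered FPKM, 67 without marker-rich libraries, 60 with the line alone and 57 with the replicate block, while DESeq2 added 44 calls and voom 42. At least 1 left-out library ended the call of 89 named results. Drd1 in neo-in cortex reversed to 0.04 without marker-rich libraries, and Rorb in neo-out striatum to 0.00 with the clock covariate; neither was then called. With an estimated correlation 148 list results lost their call. Many of the 574 list results were not called with the preset correlation, so 574 is not the base of that loss. For Het against wild type in neo-in, camera called 11, 7 and 10 lists in striatum, cortex and liver, and 4, 2 and 0 stayed called. In neo-out it called 13, 7 and 9, and 4, 2 and 0 stayed called.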

Other observations

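Mismatch repair genes moved by small amounts in striatum. Over both lines together 6 of 13 mismatch repair and repeat instability genes rose and 0 fell (8 adjusted over the list alone; median 0.11; camera adjusted p = 0.00742; adjusted p = 0.271 with an estimated correlation), 31 libraries, edgeR quasi-likelihood. Msh3, whose product acts on repeat loops, was at +0.16 ± 0.05 in neo-in, and Mlh3 at +0.16 in neo-out. The p53 target list had no common direction over both lines (1 of 14 genes higher and 3 lower, the same adjusted over the list alone; camera adjusted p = 0.594). Eda2r, a p53 target, rose by 0.76 ± 0.15 in neo-in and 0.84 ± 0.14 in neo-out, while Cdkn1a, another, fell by 0.64 and 0.44.

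In liver of the neo-out line cholangiocyte markers were lower (0 of 8 called, 3 lower over the list alone; camera adjusted p = 0.000112; adjusted p = 0.385 with an estimated correlation), and in neo-in liver stellate cell markers were higher (0 of 12 called, 4 higher over the list alone; camera adjusted p = 0.000172; adjusted p = 0.386 with an estimated correlation). In cortex interferon-stimulated genes were higher in neo-in Het mice (median 0.17; 0 of 18 called; camera adjusted p = 0.00159; adjusted p = 0.532 with an estimated correlation).

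The hypothesis on repeat length was written before its results were seen (for neo-in at a later stage), and the one on the clock score across tissues after. A longer CAG repeat was expected to give a larger striatal response in Het mice. In neo-out, repeat numbers of 193 to 208 and response scores of 0.258 to 0.336 had r = -0.32 (n = 7, exact permutation p = 0.595; rank correlation -0.11, p = 0.84; -0.14 without the 2 farthest animals). In neo-in, where the sexes did not overlap in repeat number, values less their sex mean had r = -0.05 (n = 8, exact permutation p = 0.976, rank correlation 0.14). The neo-in r was 0.76 without the 2 farthest animals, -0.40 in females and 0.96 in males. In neo-out, values less their sex mean had r = -0.43 (n = 7, exact permutation p = 0.375, rank correlation -0.40). The neo-out r was -0.98 without the 2 farthest animals, 0.15 in females and negative in males, so the lines went opposite ways there. With 7 and 8 animals the hypothesis stays open.

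If animals differed in clock phase as a whole, the clock score of 1 tissue would follow that of another within groups. It did: r = 0.51 between striatum and cortex (permutation p = 0.0204, adjusted 0.0204; rank correlation 0.47; 0.34 without the 2 farthest; 31 animals), 0.62 between striatum and liver (p = 0.00364, adjusted 0.0109; rank 0.57; 0.48) and 0.58 between cortex and liver (p = 0.00871, adjusted 0.0131; rank 0.52; 0.46; 32 animals). The result is in line with a phase shared by the tissues of an animal.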
